A study of Danio rerio with 5 samples.

How the data were processed

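Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in whole zebrafish larvae at 120 h after fertilization (5 days). The samples were 3 libraries from phenotypically normal siblings and 2 libraries from uhrf1 hi272 mutants, mutant 1 and mutant 3. Per the labels' protocols, larvae were dissociated in trypsin at 37 °C for 30 min, 50000 live cells entered each library, and reads were paired at 150 bases on a NextSeq instrument. The labels name 10 embryos in the protocol and 3 larvae per genotype in the design text. The protocol text also speaks of dissociating livers, whereas the series title, the design text and the rest of the protocol name whole larvae or embryos. Whether each library came from its own pool of larvae is not given in the sources used here. The p-values therefore measure the spread between these libraries, which may be technical. The ATAC-seq reads, the read depth and read counts were not analysed here, so the depth behind each list is unknown.

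Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic, BWA and Picard were used, and the builds named were GRCz10, mm10 and GRCm38.p4. The lists name chromosomes 1 to 25, MT and 40 unplaced scaffolds whose names begin with KN, so their coordinates were read as zebrafish GRCz10; those in the text count from 1. The peak caller and its settings are not given in the sources used here, nor is any removal of mitochondrial or duplicate reads or shift of the Tn5 insertion positions.

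The deposited values are 1 peak list per library in the broadPeak layout of 9 columns without a header, so peaks were called by library and replicates were not pooled. Each peak has a fold enrichment over background, a ratio deposited by the authors. The authors' −log10 p-value and −log10 q-value follow. The deposited score equals the whole part of 10 times the −log10 q in each of the 5366 rows. The lists were not limited to q at or below 0.05, since each held peaks above that value (66, 112 and 157 peaks in controls 1, 2 and 3, and 62 and 55 in mutants 1 and 3). Fold enrichment and q belong to their own list and were used to describe, rank or filter peaks within it. Across lists they were set side by side without a test.

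From these lists, the number of peaks, the length they cover and their median width were computed per library. Peaks of the 5 lists that overlapped by at least 1 bp were merged into regions (bedtools 2.31.1 gave the same number), and the libraries with a peak were recorded for each region. Overlap of a pair of lists was the Jaccard index, the base pairs covered in both divided by those covered in either. A value per library was compared between genotypes with a two-sided exact permutation test over the 10 ways to choose 2 of the 5 libraries (scipy 1.17.1). The smallest p it can give is 0.2, so no comparison of the 5 libraries can reach 0.05. A single region cannot reach it either, as the smallest Fisher exact p for 3 against 2 libraries is 0.1, so regions were counted and set beside the same count for other choices of libraries. Benjamini-Hochberg adjustment was applied over the 25 chromosomes and over the clusters of peaks.

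These tests, the named regions and the alternatives were fixed before the data were examined. Up to 10 regions were named among those with a peak in both mutants and no control, in all 3 controls and no mutant, and in all 5 libraries, ranked by the mean percentile of their fold enrichment within each list. The grouping of regions into clusters was chosen after seeing the data. A cluster was a run of at least 10 merged regions with gaps of at most 50 kb. Chance for the clusters on chromosomes was estimated from 100 random placements of the merged regions of chromosomes 1 to 25 on their own chromosomes, up to the highest coordinate in the lists. Alternatives were a q of at most 1e-05, lists of equal length (the 766 peaks of lowest q in each), chromosomes 1 to 25 alone, reciprocal overlap of 50%, merging within 500 bp, leaving out each library, and the replicate numbers as blocks. The counting of regions was checked on simulated lists of 720 regions. All 40 regions made in both mutants alone and all 30 made in the controls alone were recovered. The simulated regions lay far apart and none lost a peak in a library of its group. This checks the counting alone, not the power to find such regions in the real lists.

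No genome or annotation of GRCz10 was used here. Regions are therefore named by position, and the planned analyses of promoters, exons and introns, repeats, GC and CpG content and fixed gene lists were not made. For the same reason the uhrf1 locus was not examined as a check of the genotypes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.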

Results

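Accessible chromatin was mapped in whole uhrf1 hi272 mutant larvae and in their normal siblings, to ask how the genome-wide pattern of accessibility differs between the genotypes. UHRF1 recruits the maintenance DNA methyltransferase to newly replicated DNA, and hi272 is an insertional allele of its zebrafish gene. The 5 libraries held 5366 peaks in all. The sibling controls 1, 2 and 3 had 806, 1229 and 1374 peaks, and mutants 1 and 3 had 766 and 1191. Peaks on the chromosomes covered between 0.0481% and 0.0566% of the 1319 Mb that the coordinates in the lists span. Read depth behind these lists is unknown, and no interval for counting error can be given. The lists are short, and how completely they hold the accessible sites of a whole larva was not tested.

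The mutant larvae were not distinguished from their siblings by how many accessible regions were called or by how much sequence these covered. The controls had 1136 ± 295 peaks per library (SD, n = 3) and the mutants 979 ± 301 (SD, n = 2), an exact permutation p of 0.4. Peaks covered 811 ± 69.9 kb in the controls (SD, n = 3) and 817 ± 43.2 kb in the mutants (SD, n = 2), with an exact permutation p of 1. The median peak was 456 ± 137 bp wide in the controls (SD, n = 3) and 567 ± 239 bp in the mutants (SD, n = 2), with an exact permutation p of 0.6. In each genotype the library numbered 1 had the fewest and widest peaks, with median widths of 610 bp in control 1 and 735.5 bp in mutant 1, against 348 to 410 bp in the other three. Without mutant 1, the remaining mutant had 54.7 more peaks than the control mean and its median width differed from the control mean by -57.8 bp. Both directions were thus reversed in that comparison. Against the control of the same number, however, both mutants had fewer and wider peaks. Mutant 3 had 1191 peaks of median 398 bp and control 3 had 1374 of 348 bp. The labels do not say whether these numbers pair the samples. Among peaks with a q of at most 1e-05 the difference in peak number shrank from -158 to -4.83, and that in covered length widened from 5.34 to 50.3 kb. The covered length was lower in the mutants by a difference of -31.8 kb without control 1 and -25.2 kb without mutant 1.

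**Figure D1:**
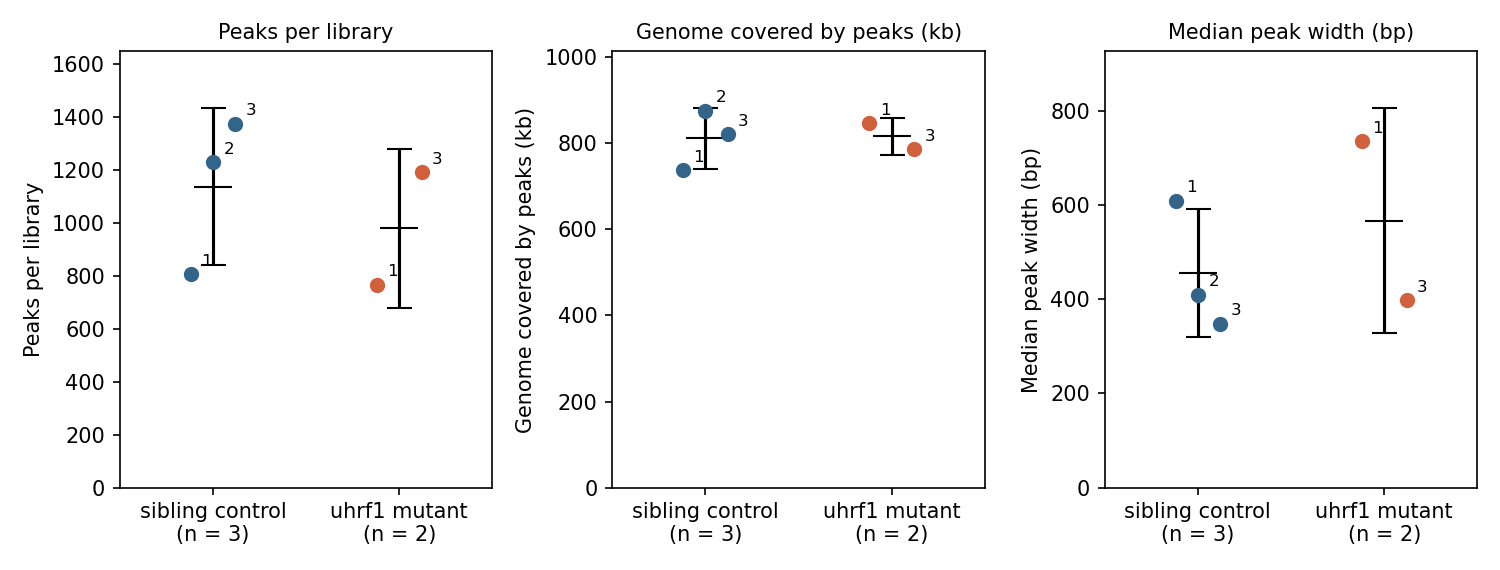
Peaks per library, length covered by peaks in kb and median peak width in bp for the 3 sibling control and 2 uhrf1 mutant libraries; points are libraries with their replicate numbers, and bars are the mean ± SD. In both genotypes library 1 has the fewest peaks (806 and 766) and the widest.

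Most of the peak length lay in regions with a peak in all 5 libraries. The 5 lists merged into 1326 regions, of which 598 (45.1%) had a peak in all 5 libraries, and 289 (21.8%) had a peak in a single library. The common regions held most of the peak length of each library, from 84.4% in control 3 to 95.1% in control 1, with 92.6% in mutant 1 and 90.3% in mutant 3. In the full lists, overlap was no higher within a genotype than across. The Jaccard index averaged 0.681 for the 3 pairs of controls (0.638 to 0.745), was 0.656 for the mutants, and averaged 0.686 for the 6 pairs of a control and a mutant (0.614 to 0.740). The difference of within-genotype and across-genotype pairs was -0.0115, and 7 of the 10 ways to divide the libraries into 3 and 2, the real one included, gave a difference at least as large. The largest, 0.0733, set control 1 and mutant 1 apart from the other three. The index of that pair was 0.693, below the 0.712 of control 1 with mutant 3. Controls 2 and 3 and mutant 3 had 0.723 to 0.745 with each other. The difference for the genotypes turned positive without control 1 (0.0226) or mutant 3 (0.0339), and among peaks with a q of at most 1e-05 (0.0018).

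The strongest regions found in all 5 libraries lay on several chromosomes. The first by rank was chromosome 20, 4437679 to 4438066, with a fold enrichment of 21.3 to 24.5 in the authors' lists. Next were chromosome 22, 39223255 to 39223527 (16.5 to 20.7), chromosome 4, 61790952 to 61791352 (15.6 to 20.7), and chromosome 17, 53292605 to 53292870 (15.6 to 18.02). The region on chromosome 18 at 13162193 to 13162412 had the widest range, from 10.8 in mutant 1 to 32.3 in control 2. The remaining 5 of the 10 were on chromosome 2 (81391 to 81997), chromosome 16 (2759143 to 2759363), chromosome 17 (39958027 to 39958712) and chromosome 21 (44162824 to 44163371 and 42661483 to 42663291), with fold enrichments between 9.002 and 15.4. The mitochondrial genome carried 1 peak in every library, which spanned from 16349 bp in mutant 1 to 16403 bp in control 3 at a fold enrichment of 1.38 to 1.43.

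Few regions were called in every library of one genotype and in none of the other. A peak in both mutants and in no control was found at 7 regions, and a peak in all 3 controls and in no mutant at 3 regions. Among the 10 pairs of libraries, 5, the mutant pair included, had at least 7 regions that the remaining libraries lacked, and the highest count was 132, for controls 2 and 3. Among the 10 sets of 3 libraries, 8, the controls included, had at least 3 such regions, with 81 as the highest, for controls 2 and 3 with mutant 3. With lists of equal length the counts for the mutants and the controls were 4 and 3. Leaving out a library loosens these definitions. The count for the mutants was then 11, 13 and 13 without control 1, 2 and 3, 61 without mutant 1 and 33 without mutant 3. The count for the controls was 135, 5 and 4 without control 1, 2 and 3, 6 without mutant 1 and 48 without mutant 3. Short lists limit both counts. Control 1 had a peak in 698 and mutant 1 in 736 of the 1326 regions, and 598 were common to all 5 libraries. The small counts therefore do not show that genotype has little effect.

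**Figure D2:**
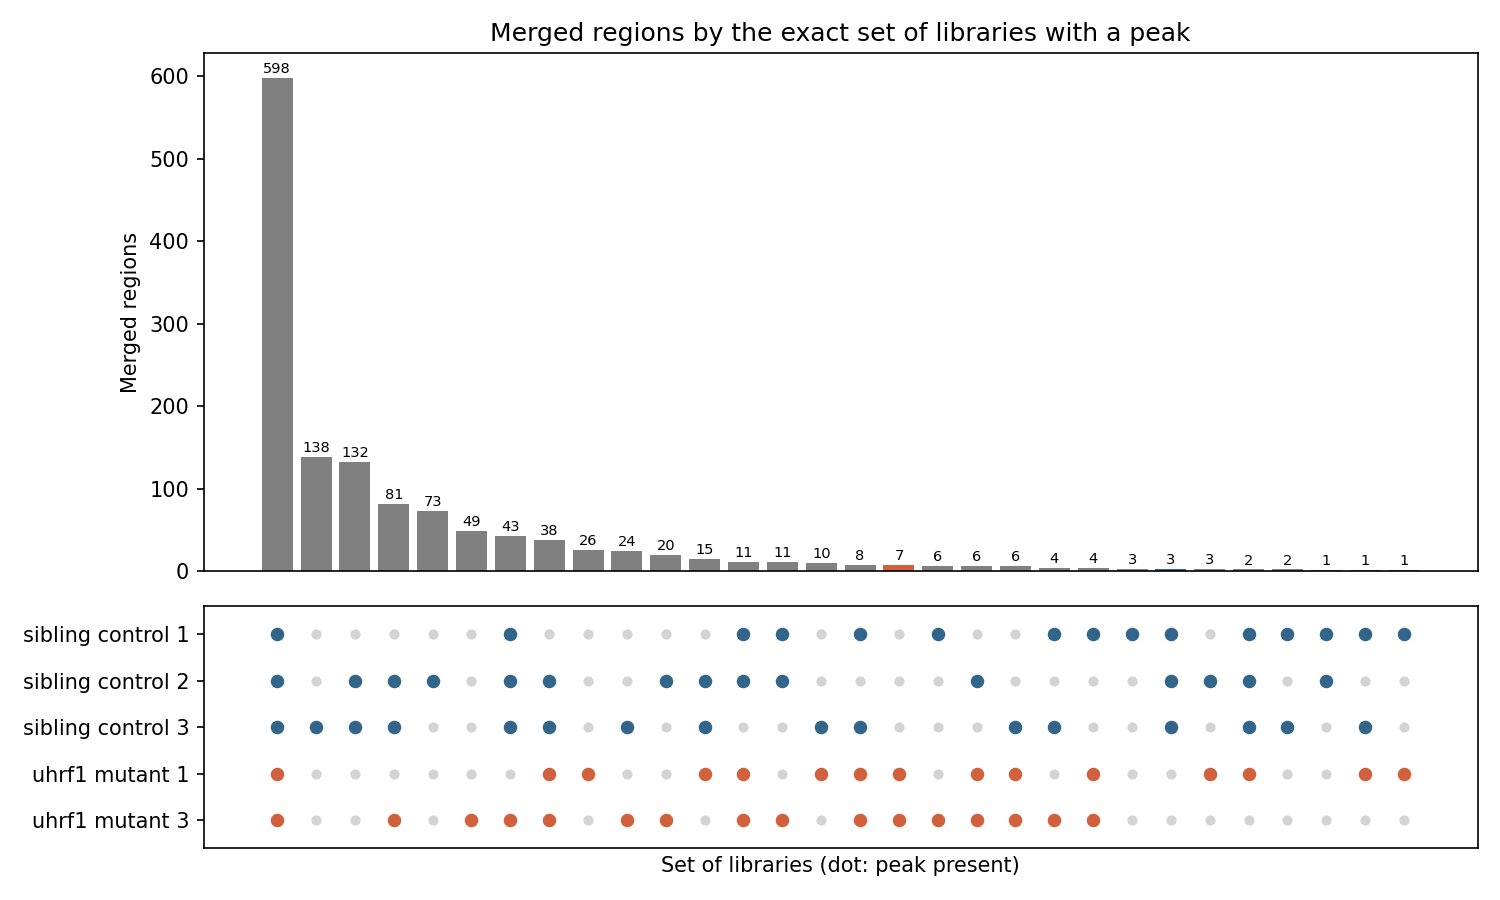
Number of merged regions (bars) for each exact set of libraries with a peak (coloured dots below each bar; blue for sibling controls, orange for uhrf1 mutants). The set of all 5 libraries holds 598 regions, and the orange bar, both mutants and no control, holds 7.

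The 2 strongest regions called only in the mutants lay 5.14 kb apart on chromosome 10. The region at 2446303 to 2447033 had a fold enrichment of 2.52 in mutant 1 and 2.62 in mutant 3, with −log10 q of 10.8 and 19.9. The region at 2452175 to 2452638 had folds of 2.06 and 2.12, with −log10 q of 4.24 and 9.32. Of the 8 merged regions between 2432620 and 2452638 on this chromosome, all had a peak in mutant 3 and 6 had a peak in a control. Mutant 1 had no peak in the regions from 2439472, 2440675, 2449179 and 2450267, where controls had peaks. The remaining 5 mutant-only regions had fold enrichments between 1.27 and 1.82. They lay on chromosome 17 (42644100 to 42644785), chromosome 16 (7273134 to 7273493 and 18348820 to 18349048), chromosome 8 (34872867 to 34873512) and scaffold KN150127.1 (14199 to 14745). All but the first chromosome 16 region lay inside clusters of peaks, where separate sites could not be told apart from signal raised along the locus. The scaffold region did not reach a q of 0.05 in either mutant, with −log10 q of 0.425 and 0.391, and the first chromosome 16 region did not in mutant 1, with 0.501.

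The 3 regions called only in the controls were short. They were scaffold KN150270.1, 21042 to 21240 (fold enrichment 2.06 to 2.26), chromosome 5, 52694890 to 52695124 (1.73 to 2.48), and chromosome 7, 45647565 to 45647765 (1.75 to 1.87). The chromosome 7 region did not reach a q of 0.05 in controls 1 and 2, where its −log10 q was 0.657 and 1.21. The chromosome 5 region did not reach it in control 2, with a −log10 q of 1.03, and lay inside a cluster of peaks.

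The called regions were concentrated in a small number of loci in both genotypes. Separate accessible sites could not be told apart there from signal raised along the whole locus. Grouping merged regions with gaps of at most 50 kb gave 24 clusters of at least 10 regions, 21 of them on chromosomes and 3 on scaffolds, with a total span of 1.90 Mb. In 100 random placements of the regions on chromosomes no such cluster arose, and the largest group held 6 regions. Random placement treats neighbouring peaks of the same locus as independent, so it shows only that the regions were not scattered evenly. The 3 scaffold clusters have no such chance value, since their regions lie within 50 kb of each other wherever they are placed. The clusters held 50.04 ± 3.59% of the peaks of a control library (SD, n = 3) and 52.99 ± 3.31% of those of a mutant library (SD, n = 2), with an exact permutation p of 0.4. The cluster on chromosome 24 at 12228574 to 12419693 had the most covered length, with 43 of its 52 regions present in all 5 libraries. It held 7.10 ± 1.05% of the covered length in controls (SD, n = 3) and 8.30 ± 0.31% in mutants (SD, n = 2), with an exact permutation p of 0.4. The cluster with the most regions, 74, was on chromosome 8 at 34517307 to 34878864, and held 3.05 ± 0.94% of the covered length in controls (SD, n = 3) and 2.43 ± 0.33% in mutants (SD, n = 2), an exact permutation p of 0.6.

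The share of covered length did not overlap between the genotypes at 5 of the 24 clusters, where chance gives 20% or 4.8. Both mutants were higher at 2 of these and lower at 3. The cluster on chromosome 12 at 14286777 to 14404212 held 4.97 ± 0.06% in the controls (SD, n = 3) and 5.50 ± 0.10% in the mutants (SD, n = 2). On chromosome 25 at 26035018 to 26065693 the shares were 0.55 ± 0.21% (SD, n = 3) and 0.91 ± 0.04% (SD, n = 2). Mutant shares were lower on chromosome 17 at 45193106 to 45242204, on chromosome 4 at 28562653 to 28627668 and on scaffold KN149692.1 at 162 to 36886. On the chromosome 4 cluster they were 1.91 ± 0.07% in controls (SD, n = 3) and 1.73 ± 0.09% in mutants (SD, n = 2). Each had the smallest exact permutation p the design allows, 0.2, and a Benjamini-Hochberg adjusted value of 0.72 over the 24 clusters.

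**Figure D3:**
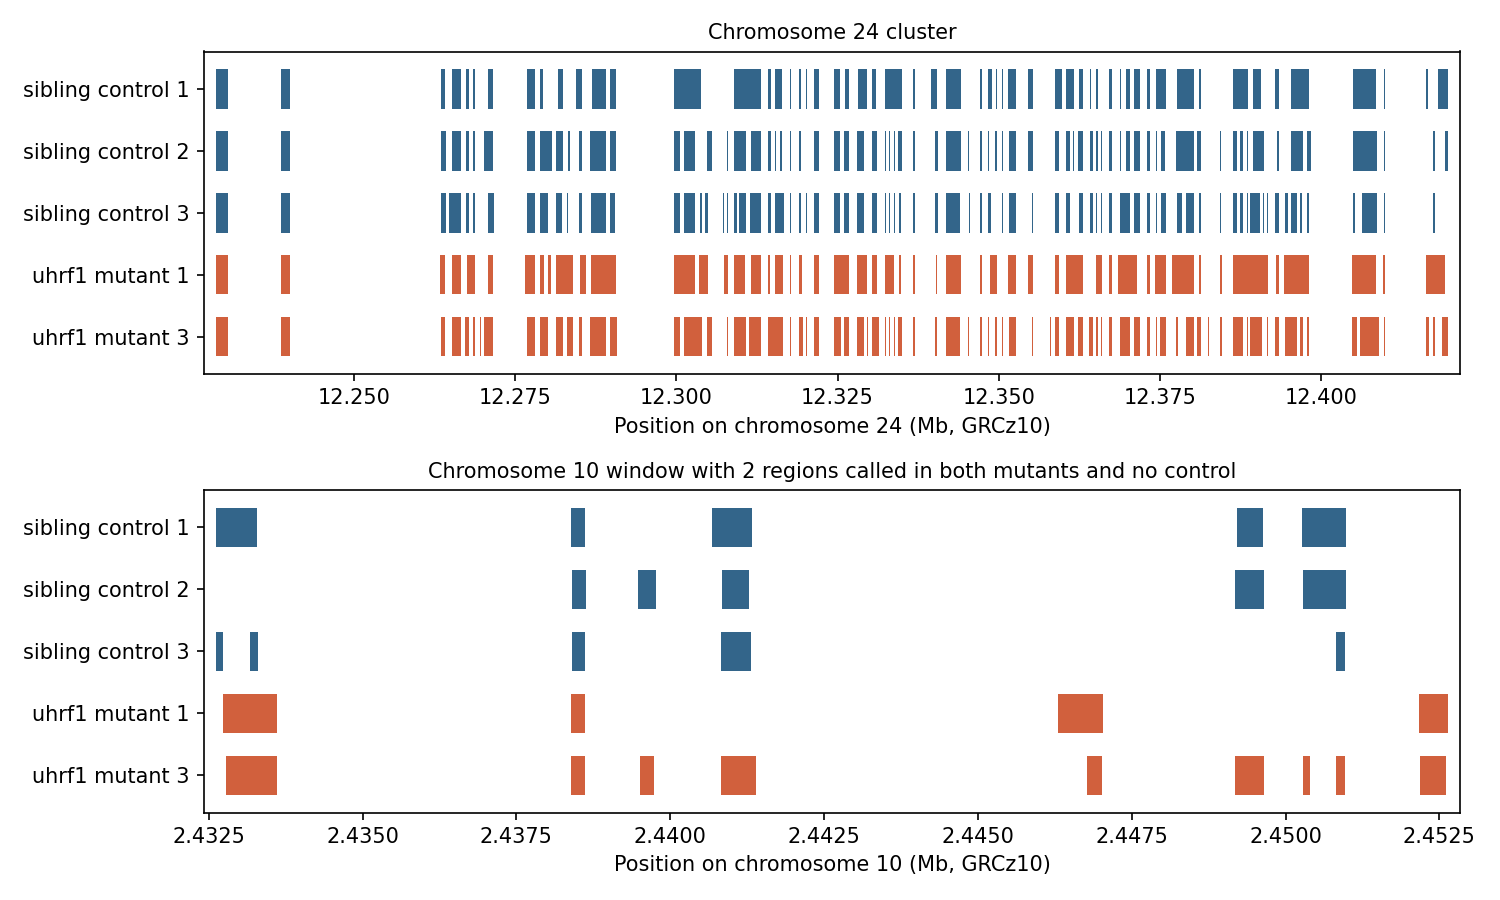
Peaks (boxes, to scale) of each library in the chromosome 24 cluster and in the chromosome 10 window, against position in Mb on GRCz10; blue marks sibling controls and orange uhrf1 mutants. The chromosome 24 peaks lie at much the same places in the 5 libraries, while on chromosome 10 the regions from 2446303 and from 2452175 have a peak in the mutants alone.

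Peaks were spread unevenly over the chromosomes in both genotypes. Chromosome 24 held 7.89 ± 0.69% of control peaks (SD, n = 3) and 7.86 ± 0.04% of mutant peaks (SD, n = 2), whereas chromosome 9 held 0.49 ± 0.15% (SD, n = 3) and 0.36 ± 0.04% (SD, n = 2). Most chromosome 24 peaks lay in its cluster, which had 56, 75 and 77 peaks in controls 1, 2 and 3. Mutants 1 and 3 had 50 and 78 peaks there. The shares of the genotypes did not overlap on 3 of the 25 chromosomes, where chance gives 20% or 5. This count was not stable, at 8 among peaks with a q of at most 1e-05 and 1 in lists of equal length. Mutant shares were higher on chromosome 15 (1.78 ± 0.26% against 1.45 ± 0.08% in controls). They were lower on chromosome 19 (0.77 ± 0.02% against 0.93 ± 0.08%) and chromosome 20 (1.97 ± 0.17% against 2.37 ± 0.16%). The smallest adjusted p of the exact permutation tests over the 25 chromosomes was 0.938. The long arm of chromosome 4 from 28 Mb, a repeat-rich and heterochromatic arm, held 4.93 ± 0.64% of control peaks (SD, n = 3) and 5.98 ± 1.33% of mutant peaks (SD, n = 2), with an exact permutation p of 0.6. Without mutant 1 the difference on this arm fell from 1.04 to 0.10 percentage points, and among peaks with a q of at most 1e-05 to 0.45. Without mutant 3 it rose to 1.98 percentage points. Many peaks counted on this arm lay between 28 and 29 Mb, next to the chosen boundary. In controls 1, 2 and 3 these were 27 of 34, 36 of 63 and 42 of 75 arm peaks. They were 22 of 53 in mutant 1 and 44 of 60 in mutant 3. The share from 29 Mb was not tested on its own. Unplaced scaffolds held 9.08 ± 0.95% of control peaks (SD, n = 3) and 9.44 ± 1.24% of mutant peaks (SD, n = 2), an exact permutation p of 0.6, and the difference turned negative without mutant 1 (-0.52 percentage points), among peaks with a q of at most 1e-05 (-1.04) and in lists of equal length (-0.46).

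**Figure D4:**
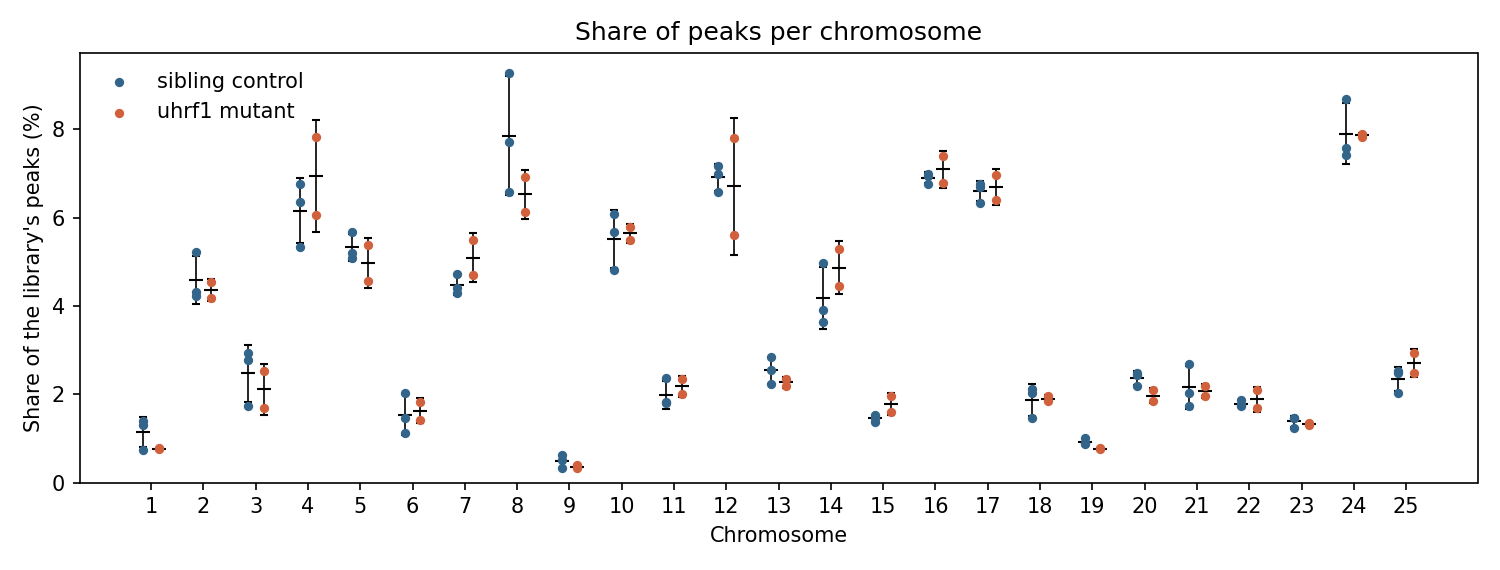
Share of each library's peaks in percent on chromosomes 1 to 25; points are libraries (blue, 3 sibling controls; orange, 2 uhrf1 mutants) and bars the mean ± SD. In these full lists the genotypes do not overlap on chromosomes 15, 19 and 20 only, where chance gives 5 chromosomes; the count was 8 among peaks with a q of at most 1e-05 and 1 in lists of equal length.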

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

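No alternative brought an exact permutation p below 0.05, which 5 libraries cannot reach, so stability here concerns direction and size only. Requiring a q of at most 1e-05 shrank the difference in peak number from -158 to -4.83, widened that in covered length from 5.34 to 50.3 kb (50.9 kb with lists of equal length), turned the difference on unplaced scaffolds to -1.04 percentage points and the Jaccard difference to 0.0018, and gave 8 chromosomes without overlap and 1 region in the controls alone. Lists of equal length gave -0.46 percentage points on scaffolds, 1 chromosome without overlap and 4 regions in the mutants alone. With reciprocal overlap of 50%, 8 regions were in the controls alone. Leaving out 1 library moved the difference in peak number between -370 and 54.7, covered length between -31.8 and 37.5 kb and median width between -57.8 and 280 bp. The difference in scaffold share moved between -0.52 and 1.23 percentage points and the Jaccard difference between -0.0444 and 0.0339. That in the share on the long arm of chromosome 4 moved between 0.10 and 1.98 percentage points. The same settings gave 3 to 12 chromosomes without overlap, where chance gives 8.33 for 2 against 2 libraries and 12.5 for 1 against 3, and 11 to 61 regions in the mutants alone, 4 to 135 in the controls alone and 601 to 692 in all. Fewer libraries raise these chromosome and region counts by construction; for the other changes the cause was not tested. The count of regions in all libraries stayed within 1.5 times 598 under each of its 12 alternatives (407 to 896). Numbers 1 and 3 occur in both genotypes, and the labels do not say whether they pair the samples. With 2 mutants the deviations mirror each other, so their correlations (0.072 for number 1, -0.022 for number 3) decide nothing, while the number 1 libraries resembled each other in peak number and width. The replicate block used numbers 1 and 3 alone and so left out control 2. Its library differences and region counts equalled those without control 2. The mean difference in peak number was -112, and 13 and 5 regions were in the mutants and the controls alone. With the block 8 chromosomes moved the same way in both pairs (12.5 by chance), and no direction changed. Leaving out number 1 of both genotypes, chosen after seeing the data, gave 79 regions in mutant 3 alone and 155 in controls 2 and 3 alone. Alternatives for promoters, repeats, base composition and gene lists were not run. The unknown read depth limits every count of peaks, since a region without a peak may have been missed.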

Other observations

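The controls differed from each other at a cluster on chromosome 8, from 34989093 to 35099497. Peaks there covered 4.98 kb in control 2 and 4.46 kb in control 3, but 0.234 kb in control 1, 1.01 kb in mutant 1 and 0.465 kb in mutant 3. None of its 13 regions had a peak in all 5 libraries, a count of 0. On chromosome 14 at 44437036 to 44515398, mutant 3 had 46 peaks and the other libraries 22 to 28. Those 46 peaks covered 10.99 kb, within the 6.75 to 15.1 kb of the others. On chromosome 4 beyond 29 Mb, control 1 had 7 peaks, controls 2 and 3 had 27 and 33, and mutants 1 and 3 had 31 and 16.

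The tests below of peak numbers within each genotype, of the genotype, of list length and of signal along whole loci were chosen only after the result was seen. The first pattern was that peak numbers differed more within genotypes than between them, with mutant 3 at 1.55 times mutant 1, and controls 2 and 3 at 1.52 and 1.70 times control 1. A surplus of weak peaks as the whole cause needed a ratio under 1.2 among peaks with a q of at most 1e-05. The ratio was 1.66 for the mutants and 1.43 and 1.62 for the controls. This cannot decide the question. A q cutoff depends on the depth of each library and may keep weaker peaks in a deeper one. Joining of neighbouring peaks in the library with wide peaks may account for the mutants, since joining peaks within 1 kb in each list left a ratio of 1.14, but was argued against as the whole cause for the controls, which stayed at 1.399 and 1.52. For the controls both outcomes rest on the longest list, whose ratio passed the bound of 1.5, while control 2 lay between 1.2 and 1.5. A rule that asked this of both lists was also tried and left both explanations open. The choice between these rules was made after the values were known. Either may still be a part of the cause. Genotype stays open as a part, since the numbers overlapped but the exact permutation p was 0.4 in a design that allows no less than 0.2. Read depth and the settings of the peak caller were not tested and may each contribute. At the first-ranked common region, on chromosome 20, folds were similar but −log10 q was 1289 and 1615 in control 1 and mutant 1. In controls 2 and 3 and mutant 3 it was 3372, 3049 and 2974. The ranked common regions on chromosomes 4 and 16 were exceptions. On chromosome 4 mutant 1, at 1019, exceeded control 2 (952) and mutant 3 (913), although its fold of 15.6 was the lowest of the 5 libraries. On chromosome 16 mutant 1 exceeded control 2 (339 against 336). At a like fold fewer reads give a lower −log10 q, so control 1 and mutant 1 may be shallower libraries. For mutant 1 the chromosome 4 region goes the other way.

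The second pattern was the 132 regions found in controls 2 and 3 alone, more in the full lists than for any other pair of libraries (24 for the next). A difference at one locus was argued against, as the cluster with the most of these regions held 6.82% of them and 116 lay outside the clusters. That cluster is on chromosome 8 at 34517307 to 34878864, near the cluster from 34989093 where the controls differed. Chromosome 8 as a whole held 18 of the 132 regions. The 132 regions were weak peaks, with a median −log10 q of 2.89 in control 2 and 2.93 in control 3, against medians of 10.5 and 11.7 over all peaks of those lists. Whether the length of these lists could account for the pattern stays open: mutant 3, with a list nearly as long as that of control 2, shared at most 24 such regions with another library, but it is a single library. The lead held among peaks with a q of at most 0.05 (93 against 27 for the next pair) but not at 1e-05 (21 against 29), nor in lists of equal length, which drop weak peaks of the longer lists by construction (12 against 65).

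The third pattern was the gathering of peaks in 24 dense clusters, of which random placement gave none of the 21 on chromosomes. One hypothesis is that signal is raised along the whole locus, as it would be from sequence held in more copies than the assembly has. Merged regions covered a median of 38.3% of a cluster's span (6.74% to 67.6%), between the bounds of 50% and 5% set for and against it, so this cannot be told apart from groups of separate accessible sites without read coverage and the genome sequence. Merged regions join the peaks of the 5 lists. The peaks of a single library covered less of the total cluster span, from 19.6% in control 1 to 23.3% in mutant 1. Peaks in clusters were no stronger than elsewhere in 4 of the 5 libraries, with a median fold enrichment of 2.08 in clusters and 2.22 outside in mutant 3. Control 3 was the exception, with 2.01 in clusters and 1.97 outside. No biological explanation of the clusters was tested.

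The smallest peak was 139 bp wide in control 1 and 162 bp in mutant 1, against 107 bp in control 2, 97 bp in control 3 and 94 bp in mutant 3.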
